A study of Mus musculus with 4 samples.

How the data were processed

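Total RNA was extracted with Trizol from GFP-positive and GFP-negative CD4 T cells of the large intestine lamina propria, biotin-labelled and hybridised to Affymetrix mouse arrays, per the labels. There were 4 arrays, 2 per group, and the group and replicate number of each came from its title. The series description writes the GFP-negative population once as lacking CD4, while the series title and the sample labels give CD4 T cells for both, and the latter were followed. The deposited values are linear probe set intensities, 1 per probe set and array. The software and summary method that made them are not given in the sources used here. On every array the mean intensity after trimming 2% of probe sets at each end was 150.0, which is the mark of scaling each array by 1 factor, while medians and other quantiles differed between arrays, so no quantile normalization had been applied. Such scaling leaves any array-wide bend between dim and bright probe sets in place. Detection calls were not used here. The median signal was 37.0 and 36.1 on the GFP-negative and 46.0 and 45.2 on the GFP-positive arrays, and the highest signals lay between 10971 and 13566.

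Values were taken to log2 after adding a pseudocount of 16. Log2 differences of genes and gene lists are on this log2(value + 16) scale unless another pseudocount is named, and understate the change of dim genes. Those of dim probe sets as a whole and of control probe sets are of log2 signals without a pseudocount. Genes were named through the platform annotation table given with the values, which can be old. Of 45101 probe sets, 64 were controls, 34958 had 1 gene symbol, 932 had several and 9211, controls included, had none here. Gene identifiers of 34754 of the one-symbol probe sets matched the RefSeq gene table, which renamed 0 of them. Each gene was represented by its probe set of highest mean over all arrays, giving 18194 genes, of which 9012 had more than 1 probe set. The 12253 genes above the 40th percentile of non-control probe sets (a signal of about 27.3) were tested, and 5941 were left out as dim. Gpr15 would have been kept at any level.

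Differences were tested two-sided with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with the group as the only term, and adjusted by the Benjamini-Hochberg method over the tested genes. The fit had 2 residual and 3.74 prior degrees of freedom. Intervals are 95% intervals from the same fit. Means ± SD are of the deposited signals of the 2 arrays of a group. Because 2 arrays per group leave few degrees of freedom, genes with a log2 difference of at least 1 and non-overlapping groups were counted as well.

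Gene lists were fixed before the data were examined. They covered regulatory, Th1, Th2, Th17, follicular helper and naive T cells, cytokines, receptors, integrins, signalling responses, general cell functions, CD4 T cell identity and markers of other cell types. Lists of at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and with camera at an estimated correlation and fry beside it. Counts of members "over the list alone" use the same fit with the adjustment made within the list.

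The rule for named genes was also set before the data were examined. It took Gpr15, then the 15 genes per direction of the largest difference among called genes with non-overlapping groups, with free places filled by uncalled genes of the smallest p that differed by at least 2-fold. It added called members and up to 3 of the brightest members of each list, and a fixed set of lineage and homing genes from Foxp3 to Cd3e. Other list members named in the text, such as Il21, Klrg1 and Zg16, were chosen after their values were seen. Some genes of the fixed set and of the lists are not reported here. Probe sets without a single gene symbol are given as counts.

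The fit was tested on simulated data for the same 12253 genes and 4 arrays, with 200 genes changed, in 20 simulations. It called 1.3% of genes changed by 1 on the log2 scale, 65.1% of those changed by 2 and 91.7% of those changed by 3, and 4.9% of calls were false, when same-numbered arrays were simulated without correlation. Deviations of same-numbered arrays correlated at 0.198 in the data, and at a simulated correlation of 0.2 the shares were 0.6%, 63.2% and 91.9%, with 2.5% of calls false. With the replicate number as a block they were then 1.3%, 70.4% and 96.1%, with 7.6% of calls false. All these shares hold for 200 changed genes spread evenly over the 3 sizes, and the share called depends on that mix. In the data 39 genes differed by at least 4-fold with non-overlapping groups and 4 genes were called. The simulated shares therefore may not carry over, and an uncalled gene may still differ by 4-fold or more. Camera with the preset correlation found a shifted list in 20 of 20 simulations and called 0 of 520 unshifted lists. With an estimated correlation it found the shifted list in 0 of 20, so its adjusted p has little power with 4 arrays. Genes were simulated independently and lists drawn at random, so these simulations cannot show how often the preset correlation calls unshifted lists of correlated genes. In the data the estimated correlation was 0.14 for the regulatory T cell list and ran from -0.13 for the mast cell list to 0.73 for the epithelial list.

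The alternatives were quantile normalization, scaling to equal medians, pseudocounts of 1 and 64, no filter and a 60th percentile filter on dim probe sets, the mean of all probe sets of a gene, eBayes with trend and robust settings, the replicate number as a block, and leaving out each array in turn. Without an array 1 group holds a single array, so the spread then comes from the other group alone, and a low p says nothing about replicates of the group with 1 array. Cyclic loess normalization, the block together with trend and robust settings, and leaving out sex-linked genes were added after the values had been seen. Figures were drawn with matplotlib 3.10.9.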

Results

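Gene expression was measured in CD4 T cells of the mouse large intestine lamina propria, the connective tissue layer under the gut epithelium. The cells came from mice of mixed 129/B6 background that carried green fluorescent protein (GFP) in 1 copy of the Gpr15 locus. Gpr15 encodes a chemoattractant receptor known for guiding T cells to the large intestine, and GFP served as the marker of its expression. Cells released by collagenase were sorted into a GFP-positive and a GFP-negative fraction, and each fraction was hybridised to 2 Affymetrix arrays, numbered replicate 1 and replicate 2. The question was how CD4 T cells that express Gpr15 differ from those that do not in the same tissue. Each array gave a signal for 45101 probe sets, and the number of arrays, 2 per group, limits the precision of every value. The labels do not say how many mice gave each sample, so p-values measure only the spread between these samples.

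Gpr15 itself followed the sort. Its signal was 154 ± 11.1 (SD, n = 2) in GFP-negative cells and 674 ± 77.9 (SD, n = 2) in GFP-positive cells, a log2 difference of 2.02 (95% interval 1.48 to 2.56). The difference was 1.97 between the replicate 1 arrays and 2.07 between the replicate 2 arrays. Its adjusted p was 0.0829, so it did not pass the threshold over all genes. T cell genes that define the sorted population were close to level, with log2 differences of -0.16 (-0.67 to 0.36) for Cd3e and -0.01 (-0.54 to 0.52) for Cd4, and Cd4 turned to 0.05 under quantile and cyclic loess normalization. The series description writes the GFP-negative cells once as lacking CD4, against its own title and every sample label, and Cd4 had mean signals of 544 in GFP-negative and 537 in GFP-positive cells.

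The replicate number marked a second split of the arrays that ran across the groups. Xist, transcribed from the inactive X chromosome, had signals of 4172 and 4313 on the GFP-negative and GFP-positive replicate 1 arrays, against 55.1 and 112 on the replicate 2 arrays. The Y-linked gene Eif2s3y had signals of 18.9 and 5.08 on the replicate 1 arrays and 2329 and 2177 on the replicate 2 arrays. These are the signals of female animals for replicate 1 and of male animals for replicate 2, so the replicates of a group came from different mice and differ in sex, while the labels do not say whether samples of equal number share mice. The added poly-A RNA control dap was bright on the GFP-negative and GFP-positive replicate 2 arrays, at 1581 and 1285, and dim on the replicate 1 arrays, at 8.59 and 53.3. Each replicate number held 1 array of each group, so differences within a number are given beside the pooled ones.

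**Figure D1:**
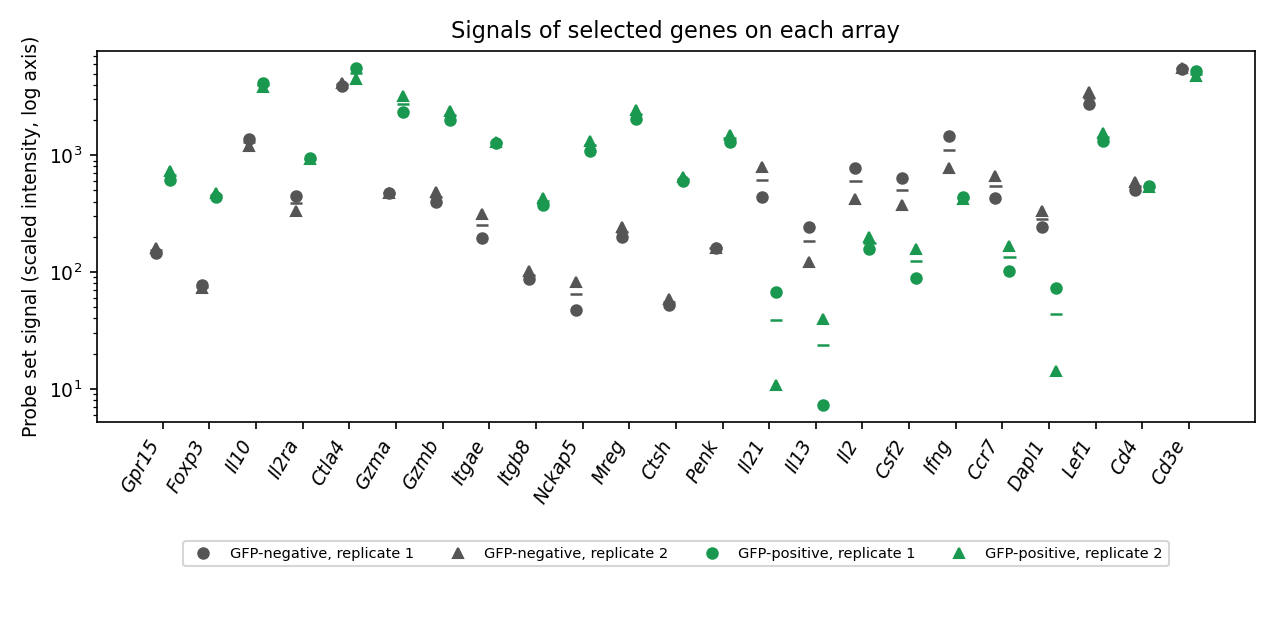
Signal of the probe set of each of a selection of the named genes (scaled intensity, log axis) on the 4 arrays, with GFP-negative arrays in grey, GFP-positive arrays in green, circles for replicate 1, triangles for replicate 2 and short lines for group means. Foxp3 had a mean of 74.4 in GFP-negative and 456 in GFP-positive cells, Il21 a mean of 611 and 38.7, and Cd3e a mean of 5529 and 4962.

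Across the genome, 4 of 12253 tested genes were called at an adjusted p under 0.05, and all 4 rose in GFP-positive cells. Nckap5 rose by 3.96 on the log2 scale, from a signal of 64.7 ± 24.6 to 1212 ± 164 (SD, n = 2 each). Mreg rose by 3.25, from 221 ± 29.7 to 2236 ± 254, and encodes melanoregulin, known from the transport of lysosome-related organelles. Ctsh, the lysosomal cysteine protease cathepsin H, rose by 3.16, from 55.7 ± 4.46 to 627 ± 32.3. Penk, the precursor of the enkephalin opioid peptides, rose by 3.0, from 160 ± 0.97 to 1394 ± 142. Their differences within the replicate numbers were 4.13 and 3.78 for Nckap5, 3.26 and 3.24 for Mreg, 3.18 and 3.15 for Ctsh, and 2.89 and 3.11 for Penk. Each had an adjusted p of 0.0397, which was 0.0527 with the replicate number as a block, and with quantile or cyclic loess normalization or without any 1 of the arrays limma called 0 genes. Their differences stayed about as large there, at 3.902 and 4.003 for Nckap5, 3.31 and 3.32 for Mreg, 3.10 and 3.19 for Ctsh and 3.02 and 3.06 for Penk under the 2 normalizations (adjusted p from 0.0636 to 0.0817), and from 2.90 for Penk to 4.27 for Nckap5 without 1 array (adjusted p from 0.167 to 0.319). At an unadjusted p under 0.05 there were then 1462 genes with quantile normalization, 1463 with cyclic loess and 1211 to 1451 without 1 array.

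No gene was called lower, while 1247 genes were higher and 536 lower at an unadjusted p under 0.05. By size, 577 genes differed by at least 2-fold with both GFP-positive arrays on the same side of both GFP-negative arrays, 416 higher and 161 lower. Under median scaling, which moved the median of all genes by -0.23 on the log2 scale, that split was 167 higher and 338 lower, and under quantile normalization 264 and 201. In all, 47.4% of genes had groups that did not overlap, where chance gives 33.3%.

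Among uncalled genes of the smallest p, the higher ones held Foxp3, the lineage transcription factor of regulatory T cells, and Gzma and Gzmb, serine proteases of cytotoxic granules. Foxp3 had a log2 difference of 2.38 (1.87 to 2.90), Gzma of 2.48 (1.88 to 3.09) and Gzmb of 2.29 (1.72 to 2.86), with adjusted p of 0.0705, 0.0745 and 0.0745. Further higher genes were Ky (3.33), the endothelin receptor gene Ednrb (3.26), Pcyt1a of phosphatidylcholine synthesis (2.75), Tmem158 (2.36), the organic anion transporter gene Slco2b1 (2.24), Ppm1l (2.13), the potassium channel gene Kcna4 (2.01) and Itgb8 (1.93). Lower genes were led by Dennd2d (-2.69), Fgf13 (-2.62), Nsg2 (-2.42), the transcription factor gene Sox4 (-2.37), Hs3st3b1 (-2.12), the interleukin-36 receptor gene Il1rl2 (-2.10) and Rflnb (-2.00). Dzip1 (-1.86), Chn2 (-1.85), Gm34006 (-1.77), AB124611 (-1.67), Actn1 (-1.66), Enc1 (-1.60), Rassf2 (-1.56) and Synpo (-1.52) completed the lower genes. Other probe sets of Ednrb, Kcna4, Slco2b1, Fgf13, Sox4, Hs3st3b1, Il1rl2, Actn1, Rassf2 and Synpo had differences of the opposite sign.

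Genes of regulatory T cells were higher as a group in GFP-positive cells. Of 25 tested members, 23 had a positive difference, the median difference was 0.86 on the log2 scale, and the competitive set test (camera) gave an adjusted p of 1.7e-09. With an estimated correlation the adjusted p was 0.527. Adjusted over the list alone, 15 members were higher and 1 lower, and over all genes 0 passed. The suppressive cytokine gene Il10 had signals of 1288 ± 128 and 3978 ± 216 (SD, n = 2), a difference of 1.62 (1.09 to 2.15). Il2ra, the high-affinity interleukin-2 receptor chain, differed by 1.24 (0.66 to 1.82), and Klrg1, a marker of terminally differentiated effector and regulatory T cells, by 2.58 (1.39 to 3.78). Ebi3, Prdm1, Ikzf4, Tnfrsf4 and Tnfrsf9 differed by 1.42, 1.42, 1.40, 1.10 and 1.16. The coinhibitory receptor gene Ctla4 was bright in both groups, at 4037 ± 158 and 5039 ± 789, with a difference of 0.31 (-0.25 to 0.87). Izumo1r, folate receptor 4 of naturally occurring regulatory T cells, was the member that was lower, by -0.96 (-1.59 to -0.33), and Gpr83 differed by -0.56 (-1.41 to 0.29). The list's median was 0.83 within replicate 1 and 0.89 within replicate 2.

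Secreted cytokine genes were lower as a group. The median of 24 tested members was -0.96, camera gave an adjusted p of 1.43e-07, and with an estimated correlation the adjusted p was 0.527. Over the list alone 13 members were lower and 3 higher, and over all genes 0 passed. Il21, the cytokine of follicular helper and Th17 cells, had signals of 611 ± 250 and 38.7 ± 39.6 (SD, n = 2), a difference of -3.68 (-5.11 to -2.25). The T cell growth factor gene Il2 differed by -1.61 (-2.45 to -0.77) and the myeloid growth factor gene Csf2 by -1.90 (-2.80 to -0.997). Cd40lg and Tnfsf11, ligands of the tumour necrosis factor family, differed by -1.17 and -0.94. The 3 higher members were Il10, Ebi3 and Tgfb1. The list's median was -1.24 within replicate 1 and -0.71 within replicate 2. Without GFP-positive replicate 1 there were 4 lower members adjusted over the list alone, and without GFP-negative replicate 1 there were 5.

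The helper lineages were compared list by list. Th1 genes had a median of -0.19 over 14 members (camera adjusted p = 0.0637), with -0.58 within replicate 1 and 0.20 within replicate 2. The list passed in 3 of 16 alternative fits, among them those without GFP-positive replicate 2 (median -0.41, adjusted p = 0.0135) and without GFP-negative replicate 2 (-0.36, 0.0212), while without GFP-positive replicate 1 the median was 0.04 (0.316). The 4 members lower over the list alone were Ifng at -1.27 (-2.10 to -0.43), its transcription factor gene Tbx21 at -1.42 (-2.31 to -0.53), Eomes at -1.13 and Fasl at -1.59. Th2 genes had a median of -0.16 over 11 members (camera adjusted p = 0.0637), and the type 2 cytokine genes Il13 and Il5 were lower over the list alone, at -2.40 and -1.93. The Th2 list passed in 2 of 16 alternative fits, with an adjusted p of 0.0212 without GFP-negative replicate 2 and 0.0263 without the dim filter, and its median ran from -0.39 to -0.10 over the 16. Gata3, the Th2 lineage factor that regulatory T cells also express, differed by 0.73 (-0.18 to 1.65). Th17 genes went both ways, with a median of 0.34, a mean of -0.08 and a camera adjusted p of 0.876 over 11 members. Of these, Ahr, Ccl20 and Ltb4r1 were higher over the list alone, at 0.90, 1.10 and 1.59, and Il21 was lower. Il17a differed by -0.75 (-1.45 to -0.05) and did not pass.

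Follicular helper T cell genes had a median of -0.51 over 14 members (camera adjusted p = 0.00449), and the adjusted p was 0.527 with an estimated correlation. Over the list alone Btla, Il6ra, Slamf6 and Sostdc1 were lower, at -1.32, -1.58, -1.10 and -1.92, and Pdcd1 was higher at 1.06. Another probe set of Sostdc1 differed by 0.26. The brightest members, Bcl6, Tox2 and Tox, differed by -0.14 (-0.69 to 0.41), 0.28 (-0.29 to 0.84) and 0.58 (0.04 to 1.12), with another probe set of Tox2 at -0.33. Cxcr5, the follicle homing receptor gene, was dim and differed by -0.03 (-0.997 to 0.933). Without GFP-negative replicate 2 the list's median was -0.22 and its adjusted p 0.0676, and without GFP-positive replicate 1 they were -0.26 and 0.0135.

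Genes of naive and central memory T cells were lower in GFP-positive cells. The median of 14 members was -0.72 (camera adjusted p = 4.0e-06), with -0.76 and -0.68 within the replicate numbers, and with an estimated correlation the adjusted p was 0.527. Over the list alone 7 members were lower and 0 higher, and over all genes 0 passed. Ccr7, which guides T cells to lymph nodes, had signals of 547 ± 161 and 134 ± 45.7 (SD, n = 2), a difference of -1.91 (-2.72 to -1.10). Lef1, a transcription factor of naive T cells, differed by -1.11 (-1.69 to -0.52), Bach2 by -1.45, Igfbp4 by -1.37, Klf3 by -0.74 and Dapl1 by -2.52 (-3.81 to -1.24). Of the 7 probe sets of Klf3 the differences ran from -1.60 to 0.28. Without GFP-negative replicate 2 there were 3 lower members over the list alone, and without GFP-positive replicate 1 there were 4.

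Receptors for chemoattractants and trafficking signals did not move together. The median of 27 tested members was 0.15, turning to -0.08 under median scaling, and the camera adjusted p was 0.329, which was 0.0495 in 1 of 16 alternative fits, the replicate block with trend and robust settings. Over the list alone 4 were higher, namely Gpr15, Ccr1 at 1.76, the leukotriene B4 receptor gene Ltb4r1 at 1.59 and Gpr65 at 0.88, and 2 were lower, namely Ccr7 and Gpr18 at -1.13. The gut homing receptor gene Ccr9 differed by 0.93 (-0.15 to 2.01), Ccr6 by 0.63 (0.01 to 1.26) and Ccr8 by 1.2 (0.29 to 2.11). Among 15 integrin and selectin ligand genes the median was 0.13, or -0.10 under median scaling (camera adjusted p = 0.346, or 0.0245 in that same fit). Over that list alone Itgae, whose product CD103 binds E-cadherin on epithelium, and Itgb8, whose product activates latent TGF-beta, were higher. Itgae had signals of 254 ± 81.4 and 1285 ± 16.3 (SD, n = 2), a difference of 2.31 (1.62 to 2.98), and Itgb8 of 94.4 ± 11.3 and 404 ± 41.7. Itga4 and Itgb7, which encode the gut homing integrin alpha4beta7, differed by 0.54 (0.00 to 1.08) and 0.62 (0.02 to 1.22) and did not pass.

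Genes of the TGF-beta response went both ways, with a median of 0.29 over 18 members and a camera adjusted p of 0.92. The median was 0.14 under quantile normalization, 0.13 under cyclic loess and 0.06 under median scaling. Over the list alone Itgae, Tgfb1 and Tgfbr1 were higher and Smurf2, Tgfbr2 and Tgfbr3 lower, the receptor genes at 0.87, -0.76 and -1.43, and Tgfbr2 turned to 0.07 with the mean of its probe sets. Other probe sets of Tgfbr1 and Tgfbr2 went as far as -0.06 and 0.73. The list of targets of the aryl hydrocarbon receptor, a sensor of dietary and microbial ligands, had a median of 1.09 over 5 members. Ahr, the gene of the receptor itself and no target, is 1 of the 5 and also belongs to the Th17 list. Camera gave an adjusted p of 0.00764 for the target list. The adjusted p was 0.527 with an estimated correlation. Over the list alone Ahr, Cyp1a1 and Nqo1 were higher, at 0.90, 1.21 and 1.09. All 5 members were highest on GFP-positive replicate 2, the array with the highest myeloid markers, and without it the median was 0.75 and the adjusted p 0.111. Without GFP-negative replicate 1 the median was 0.72 and the adjusted p 0.0722.

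Inhibitory receptor genes had a median of 0.30 over 12 members (camera adjusted p = 0.0637), and the list passed in 7 of 16 alternative fits, none of them among the 4 without 1 array. Its median ran from 0.07 under median scaling to 0.60 with the mean of probe sets. Havcr2, Pdcd1, Cd200r1 and Lag3 were higher over the list alone, at 1.46, 1.06, 0.96 and 0.87, and Btla was lower. Cytotoxic and natural killer receptor genes had a median of -0.25 over 17 members (camera adjusted p = 0.0751), or -0.46 under quantile normalization and -0.48 under cyclic loess and median scaling, with Gzma and Gzmb higher and Crtam and Fasl lower over the list alone. Without GFP-positive replicate 2 the cytotoxic list passed (median -0.37, adjusted p = 0.0458). Immediate-early genes of T cell receptor signalling had a median of -0.02 over 29 members (camera adjusted p = 0.0637), which was 0.02 under quantile normalization, 0.05 under cyclic loess and 0.03 without GFP-positive replicate 2. The list passed as lower in 3 of 16 alternative fits, namely under median scaling (median -0.26, adjusted p = 0.0407), without the dim filter (-0.02, 0.048) and without GFP-positive replicate 1 (-0.19, 0.0065). Of its members Dusp4 was higher over the list alone, at 1.58, and Egr2, Egr3 and Myc were lower, at -1.09, -1.09 and -0.92, with another probe set of Egr3 at 0.35.

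Among lists of general cell functions, ribosomal protein genes had a median of -0.22 over 21 members (camera adjusted p = 5.9e-04), heat shock and dissociation stress genes -0.32 over 16 (0.00599), cell cycle genes -0.15 over 29 (0.0042) and type I interferon response genes -0.28 over 17 (0.012). With an estimated correlation the adjusted p was 0.535 for the heat shock list and 0.527 for the other lists of this group, and 0 members of each passed over the list alone. The ribosomal list had medians of -0.15 and -0.41 within the replicate numbers, and of -0.12 without GFP-positive replicate 2 (adjusted p = 0.0458) and -0.35 without GFP-positive replicate 1. The call was lost without GFP-positive replicate 2 for the heat shock list, where its median was -0.02, against -0.54 without GFP-positive replicate 1 and -0.21 without GFP-negative replicate 1. For the interferon list it was lost without that array or without GFP-negative replicate 1, with medians of -0.13 and -0.08, and it held in 12 of 16 alternative fits. For the cell cycle list it was lost without GFP-negative replicate 2 or GFP-positive replicate 1, with medians of -0.08 and -0.06, against -0.33 without GFP-negative replicate 1 and -0.23 without GFP-positive replicate 2. Glycolysis genes had a median of 0.23 over 16 members, which was -0.004 under median scaling, and cholesterol synthesis genes -0.08 over 15, with camera adjusted p of 0.213 and 0.246. The glycolysis list passed as higher under quantile normalization (median 0.26, adjusted p = 0.0262) and cyclic loess (0.28, 0.0267). The CD4 T cell identity list had a median of -0.07 over 18 members (camera adjusted p = 0.0302, and adjusted p = 0.527 with an estimated correlation). That median was -0.005 under quantile normalization, 0.005 under cyclic loess and -0.297 under median scaling, with camera adjusted p of 0.311, 0.349 and 0.016. The call held in 10 of 16 alternative fits. It was lost without GFP-negative replicate 1, GFP-negative replicate 2 or GFP-positive replicate 2, with medians of -0.11, -0.14 and -0.10.

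**Figure D2:**
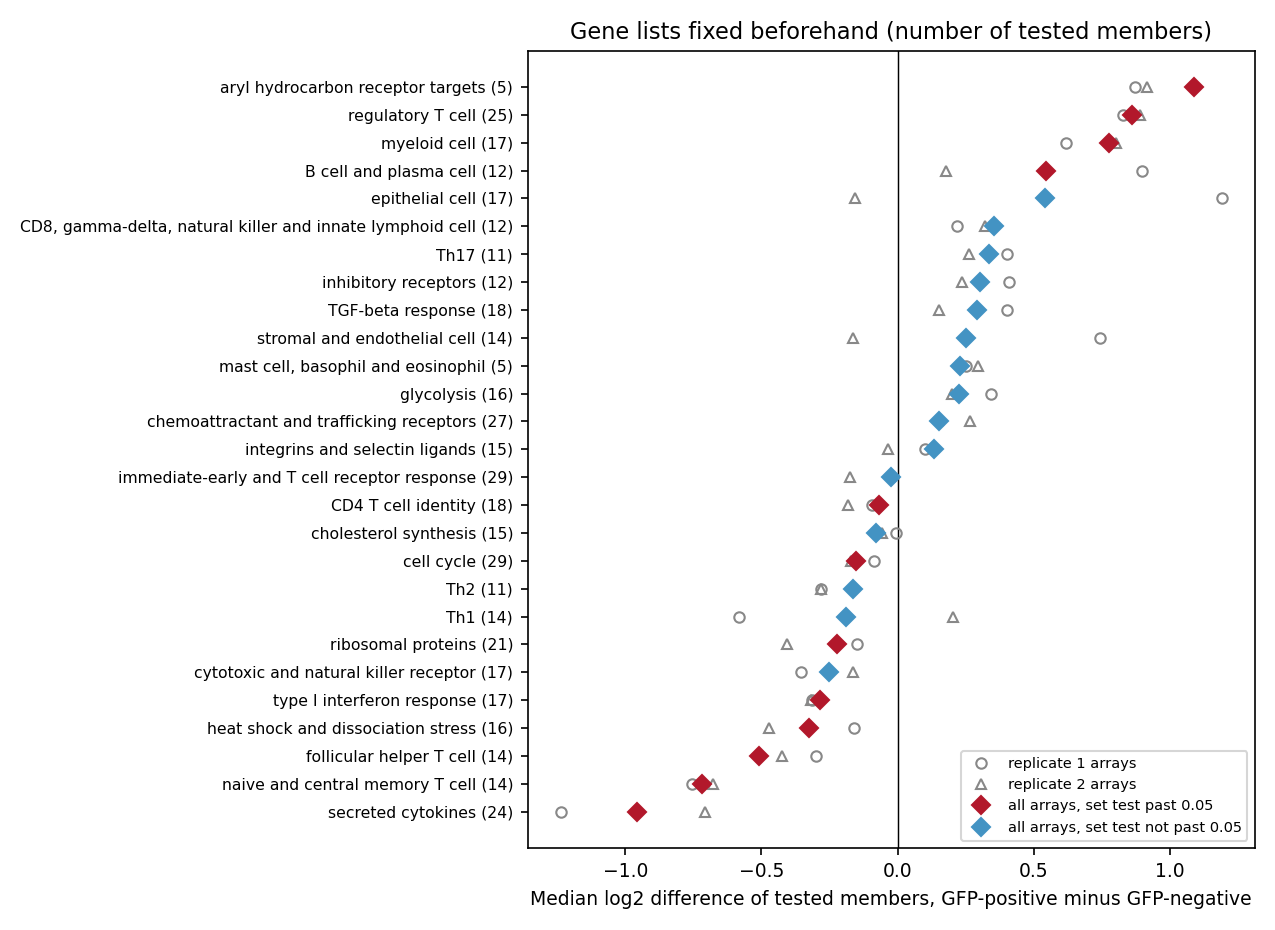
Median log2 difference of the tested members of each gene list, GFP-positive minus GFP-negative, with the number of tested members in brackets. Diamonds use all 4 arrays, in red where the camera adjusted p was under 0.05 and in blue otherwise, open circles the replicate 1 arrays and open triangles the replicate 2 arrays, and the regulatory T cell list lay at 0.86 and the secreted cytokine list at -0.96.

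Markers of other cell types were also measured. Myeloid markers had a median of 0.78 over 17 members, all 17 with a positive difference (camera adjusted p = 0.00189, and adjusted p = 0.527 with an estimated correlation). The complement gene C1qb had signals of 13.7 and 85.0 on the GFP-negative arrays and 26.4 and 700.4 on the GFP-positive arrays, replicate 1 first. Csf1r, the receptor of macrophage colony-stimulating factor, had 7.73, 10.7, 35.5 and 164 in the same order. The differences of its 3 probe sets ran from 0.09 to 1.93, and those of the 3 of C1qb from 0.56 to 1.67. The list's median was 0.62 and 0.80 within the replicate numbers, and without GFP-positive replicate 2 it was 0.29 with an adjusted p of 0.113. Without GFP-negative replicate 1 the median was 0.51 and the adjusted p 0.146, and without GFP-positive replicate 1 or GFP-negative replicate 2 the medians were 1.31 and 1.19. Markers of B and plasma cells had a median of 0.54 over 12 members (camera adjusted p = 0.0193, and adjusted p = 0.527 with an estimated correlation), with 0.90 and 0.18 within the replicate numbers. The call was lost without GFP-negative replicate 1 (median 0.26) or GFP-positive replicate 1 (median 0.54). Jchain, the joining chain of secreted immunoglobulin A and M, was bright on all arrays, at 4154 ± 426 and 5156 ± 1503 (SD, n = 2).

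Epithelial markers had a median of 0.54 over 17 members and did not pass (camera adjusted p = 0.0546), with 1.19 within replicate 1 and -0.16 within replicate 2. The list passed in 8 of 16 alternative fits, with an adjusted p of 0.0273 when the replicate number was a block, and its median was -0.26 without GFP-positive replicate 1 and 1.28 without GFP-positive replicate 2, where a single GFP-positive array stands for its group. Zg16, a secreted protein gene of goblet cells, had signals of 172 and 221 on the GFP-negative arrays and 941 and 82.4 on the GFP-positive arrays, replicate 1 first, and the differences of its 3 probe sets ran from -0.04 to 0.78. Epcam was the member higher over the list alone, at 1.64. Stromal and endothelial markers had a median of 0.25 over 14 members with a camera test in the opposite direction (adjusted p = 0.92), and 0.74 and -0.16 within the replicate numbers. That list passed as lower without GFP-negative replicate 1 (median -0.35, adjusted p = 0.0251) and as higher without GFP-negative replicate 2 (median 0.85, adjusted p = 0.0195). Markers of mast cells, basophils and eosinophils had a median of 0.23 over 5 members, a mean of -0.04 and a camera test in the negative direction (adjusted p = 0.92). The median turned to -0.08 under quantile normalization, and Hdc was lower over that list alone, at -2.40. Markers of CD8, gamma-delta, natural killer and innate lymphoid cells had a median of 0.35 over 12 members (camera adjusted p = 0.833). As 8 of the 21 genes of this fixed list belong to another fixed list as well, its median does not read other cell types alone. Of the erythroid and platelet list 2 members were tested, with a median of 0.36 and no set test.

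**Figure D3:**
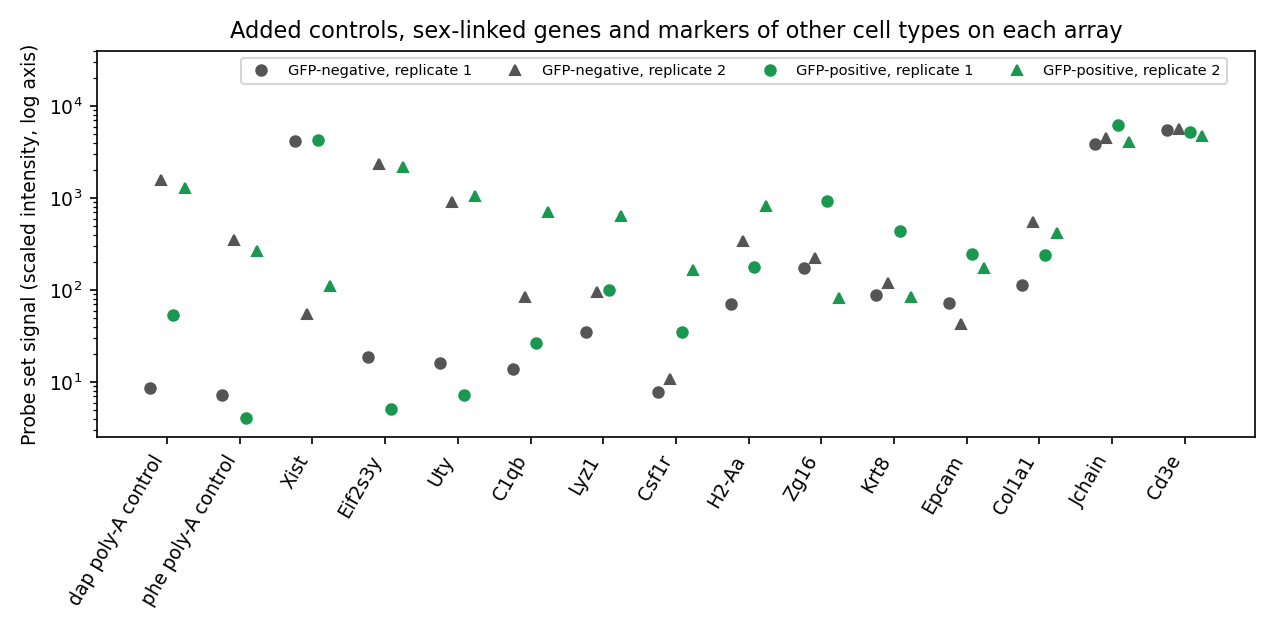
Signals (scaled intensity, log axis) of 2 added poly-A controls, 3 sex-linked genes, markers of myeloid, epithelial, stromal and plasma cells and Cd3e on the 4 arrays, with the same symbols as in the plot of selected genes. The dap control lay at 1581 and 1285 on the replicate 2 arrays, C1qb was highest on GFP-positive replicate 2 at 700.4 and Zg16 on GFP-positive replicate 1 at 941.

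As a sign of RNA quality, the log2 signal of the 3' probe set minus the 5' probe set of actin was 1.37 and 2.20 on the GFP-negative arrays and 1.97 and 2.29 on the GFP-positive arrays, replicate 1 first, where larger values mean a stronger loss of 5' signal, so it was larger in GFP-positive cells within both replicate numbers. For GAPDH the values were 0.38, 0.55, 0.62 and 0.46, larger in GFP-positive cells within replicate 1 and smaller within replicate 2. The median signal over all probe sets was 37.0 and 36.1 on the GFP-negative arrays and 46.0 and 45.2 on the GFP-positive arrays, and so differed between the groups more than within them.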

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

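The tests of scaling and of RNA quality in this part were chosen after the results they bear on had been seen, and the test of the replicate numbers before.

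Poly-A RNA controls, which the comparison does not use, were bright on the replicate 2 arrays, where dap had a signal of 1581.2 in GFP-negative and 1285.3 in GFP-positive cells. On the replicate 1 arrays dap lay at 8.59 and 53.3. The controls lys, phe and thr split the arrays in the same way, with phe at 354 and 265 on the replicate 2 arrays and 7.28 and 4.11 on the replicate 1 arrays.

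Probe sets without a single gene symbol, which the gene comparison leaves out, were counted in the same way. Of 5508 above the dim limit, 187 were at least 2-fold higher and 90 at least 2-fold lower in GFP-positive cells with non-overlapping groups. Tested with limma together with the named probe sets, 0 were called at an adjusted p under 0.05, and 798 of the 5508 had an unadjusted p under 0.05. The shares were similar among the 12253 tested genes. Of these 416 were higher and 161 lower by the same size rule, and 1783 had an unadjusted limma p under 0.05. For the genes that split turned to 167 higher and 338 lower under median scaling.

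Dim probe sets were brighter on the GFP-positive arrays. Probe sets below the median signal had a median log2 difference of 0.38 and those above it of 0.06. Differences in this paragraph are of log2 signals without the pseudocount, so their size cannot be set beside those of the gene lists. A factor that shifts all probe sets alike is argued against by the 9 hybridization controls, whose differences ran from -0.03 to 0.11 with a median of 0.003. These controls are bright and were read after scaling, so they cannot tell whether a larger factor lifted only the dim signals, which stays open. The lowest signal was 0.149 and 0.148 on the GFP-negative arrays and 0.205 and 0.207 on the GFP-positive arrays. The dim probe sets were brighter by 0.395 within replicate 1 and 0.357 within replicate 2. A labelling batch that separates the replicate numbers would hold 1 array of each group. It could not raise the GFP-positive arrays alike within both numbers, so the design, more than these values, argues against it. The values say nothing about a labelling batch that follows the groups, and the labels give none. Shorter labelled target on the GFP-positive arrays stays open, since their lowest actin 3' to 5' difference was 1.97 and the GFP-negative arrays lay at 1.37 and 2.20, with a larger value in GFP-positive cells within both replicate numbers, and so does a biological difference in the mixture of transcripts, which may raise many dim genes and was not tested.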

How the results depend on the processing

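Of 130 named genes followed over the 16 alternative fits, 121 kept their sign in all of them. The regulatory T cell, naive T cell, secreted cytokine and ribosomal lists passed camera at the preset correlation in 16 of 16, and did not pass with an estimated correlation. The count of calls moved most. It was 0 with quantile normalization, cyclic loess, a pseudocount of 1, no dim filter, the replicate block, all probe sets tested, and without any 1 array (0 to 0), where 1 residual degree of freedom was left. Among these fits of genes, limma gave 1211 to 2129 genes at an unadjusted p under 0.05, and 3523 of all probe sets. It was 174 (100 higher, 74 lower) with a pseudocount of 64, 50 (40 and 10) with the stricter dim filter, 241 (144 and 97) with trend and robust settings and 1323 (691 and 632) with the replicate block and those settings together. It was 27 at an adjusted p under 0.1, and 6 with the mean of probe sets, 1 of them lower. The 4 called genes were kept in each of these fits that made calls and under median scaling, which called the same number. The causes were not tested, except that trend and robust settings and the pseudocount change the spread assigned to each gene by construction.

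The labels do not say that equal replicate numbers share mice, and deviations of same-numbered arrays correlated at 0.198 across genes (0.168 without sex-linked genes). With the replicate block 0 genes were called by limma, 34 at an adjusted p under 0.1 and 2129 at an unadjusted p under 0.05. This block ended no list's call and added the epithelial list (adjusted p = 0.0273). The block with trend and robust settings ended the call of the type I interferon list (0.0615) and added the epithelial (0.00245), Th1 (0.0146), integrin (0.0245) and chemoattractant receptor (0.0495) lists. Splitting the 4 arrays by replicate number, across which sex and the poly-A controls also differ, gave 3 calls and 221 genes of at least 2-fold. The crossed split, which joins the GFP-positive array of 1 number with the GFP-negative array of the other, gave 0 and 89. The real groups gave 4 and 577, and the 3 possible splits are too few for a share under 0.05.

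Genes of at least 2-fold numbered 1103 with a pseudocount of 1, 183 with 64, 897 without the dim filter, 351 with the stricter filter, 367 with the mean of probe sets, 39 at 4-fold, and 759 to 932 without 1 array. The higher ones were 264 with quantile normalization, 259 with cyclic loess, 167 with median scaling, 862 and 107 with pseudocounts of 1 and 64, 683 and 232 with no and the stricter filter, 274 with the mean of probe sets and 512 to 670 without 1 array. The lower ones were 338, 76 and 93 with median scaling, a pseudocount of 64 and the mean of probe sets, and 202 to 302 without 1 array. Gpr15 passed the threshold with a pseudocount of 64 (1.76) and, at 2.02, with the stricter filter and with trend and robust settings, with or without the block. With camera at an estimated correlation or the directional test of fry 0 lists passed. The test of fry for change in either direction had adjusted p under 0.05 for lists such as inhibitory receptors (0.00297), CD4 identity (0.00338), regulatory T cell genes (0.0154) and secreted cytokines (0.0197), and not for others such as myeloid markers (0.533).

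Signs turned for Cd4 (0.051 with quantile, 0.049 with cyclic loess, -0.12 to 0.10 without 1 array) and Tgfbr2 (0.073 with the mean of probe sets). Without 1 array the ranges were -0.74 to 1.37 for Col1a1, -0.51 to 0.45 for Cxcr5, -0.20 to 0.84 for Igha, -0.018 to 0.58 for Jchain, -0.26 to 1.93 for Krt8, -1.10 to 2.18 for Zg16 and -0.37 to 3.71 for C1qb. The set test turned its direction for some lists that did not pass with all 4 arrays, here with their medians. These were CD8 and innate lymphoid (0.26 without filter, 0.18 with the stricter filter, 0.17 to 0.43 without 1 array), TGF-beta (0.29 with the replicate block, 0.09 to 0.31 without 1 array), Th17 (-0.085, 0.35 and 0.34 with the stricter filter, mean of probe sets and block with trend, 0.14 to 0.31 without 1 array) and cytotoxic genes (-0.25 with block and trend). Epithelial genes ran from -0.26 to 1.28 without 1 array. Mast cell genes stood at 0.00, 0.32 and 0.23 with median scaling, a pseudocount of 1 and the mean of probe sets, at 0.23 with fry and at 0.093 to 0.44 without 1 array. Stromal genes stood at 0.023, 0.34, 0.11 and 0.31 with median scaling, pseudocounts of 1 and 64 and the stricter filter, at 0.25 with trend, block or fry, and at -0.35 to 0.85 without 1 array, passing as lower without GFP-negative replicate 1 (adjusted p = 0.0251) and as higher without GFP-negative replicate 2 (0.0195). Cytotoxic genes passed without GFP-positive replicate 2 (-0.37, adjusted p = 0.0458). Th1 genes passed in 3 of 16 fits and ran from -0.41 to 0.037 without 1 array, Th2 genes passed in 2 and immediate-early genes in 3. These causes were not tested. Signals near 27.3, the dim limit, bound what can be read for Cxcr5. The same holds for the size of difference of genes whose mean lay below it in 1 group. Examples in GFP-positive cells were Il1rl2 (6.85), Chn2 (9.11), Crtam (13.5), Fgf13 (14.7), Synpo (17.1) and Il13 (23.5). In GFP-negative cells they were Csf1r (9.23), Ltb4r1 (16.8), Kcna4 (17.0) and Cyp1a1 (17.4).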

Other observations

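Among genes outside the fixed lists, chosen after their values were seen, Hopx, a homeodomain protein gene known from effector T cells and induced regulatory T cells, had signals of 770 ± 121 in GFP-negative and 2789 ± 244 in GFP-positive cells (SD, n = 2), a log2 difference of 1.84 (95% interval 1.27 to 2.41). The syndecan gene Sdc4 differed by 1.71 (1.18 to 2.24) and the antioxidant gene Srxn1 by 1.77 (1.25 to 2.29). Lower genes were chosen in the same way. Themis, a thymocyte and T cell signalling adaptor, differed by -1.69 (-2.35 to -1.03), the protein kinase C theta gene Prkcq by -1.17 (-1.71 to -0.63), the survival gene Bcl2 by -1.57 (-2.20 to -0.94), Pik3ip1, an inhibitor of phosphoinositide 3-kinase, by -1.49 (-2.12 to -0.85) and Dpp4, which encodes CD26, by -1.19 (-1.73 to -0.65), with another of its probe sets at 0.34. The chemokine gene Xcl1 differed by -1.60 (-2.34 to -0.85). None of these passed over all genes, with adjusted p from 0.0942 to 0.167, and each differed the same way within both replicate numbers.

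The test of dim probe sets and both tests of cytokines in this part were chosen after the results had been seen, and the lists of further macrophage and epithelial genes were written before their values were read.

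Markers of myeloid cells were highest on GFP-positive replicate 2, although the cells were sorted on CD4. The list's median level was 5.68 and 6.49 on the GFP-negative arrays and 6.28 and 7.49 on the GFP-positive arrays (log2, replicate 1 first), so GFP-positive replicate 1 lay below GFP-negative replicate 2. The brightness of dim probe sets as the whole cause is argued against, since the myeloid list still had a median log2 difference of 0.625 under cyclic loess. RNA of myeloid cells in GFP-positive replicate 2 is a candidate explanation, since 9 of 16 tested genes of a second macrophage list, or 56.2%, were highest on that array, against 27.1% of all tested genes. Genes of 1 cell type vary together, so no p is given for this share. The comparison with all tested genes was not matched for signal, and dim probe sets were brighter on the GFP-positive arrays, which may account for part of the excess. Of the other members, 4 were highest on GFP-positive replicate 1 and 3 on GFP-negative replicate 2. On GFP-positive replicate 2 C1qb had a signal of 700.4 and Lyz1 of 639. Of the 24 genes of the fixed list 2 belong to another fixed list as well, and Selenop and Ms4a6c of the second list were bright on all arrays. For the fixed list 14 of 17 members were highest on GFP-positive replicate 2, and whether such cells entered the GFP-positive gate through their own fluorescence was not tested.

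Epithelial markers set the other GFP-positive array apart. Of a second list of epithelial genes, 18 of 22 tested, or 81.8%, were highest on GFP-positive replicate 1. The share of all tested genes, again not matched for signal and without a p, was 29.6%. RNA of epithelial cells in that array may account for this, although a sort on CD4 would remove such cells. The list's median lay at 7.08 on that array and between 5.95 and 6.26 on the others (log2). The fixed epithelial list shares 0 of its 24 genes with another fixed list.

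The lower cytokine genes are weighed last. Dilution of T cell RNA by RNA of other cells is argued against as the whole cause. The CD4 T cell identity list had a median of -0.067 (quartiles -0.33 and 0.02), against -0.96 for the cytokine list. Under median scaling these medians were -0.297 and -1.188. Of the 18 tested identity genes 13 were lower, so a partial dilution stays open. Weaker recent stimulation of the GFP-positive cells stays open, since 79.3% of the immediate-early genes, 23 of 29, lay within 0.3 of no difference while Egr2, Egr3 and Myc were lower. The immediate-early list had a median of -0.025 and passed as lower in 3 of 16 alternative fits, with -0.255 under median scaling and -0.193 without GFP-positive replicate 1. The difference between the sorted populations that the design names, which may hold cells of different lineages, stays open and was not tested separately.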
